A study of Mus musculus with 6 samples.

How the data were processed

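Tailbud tissue was cut from mouse embryos at embryonic day 9.5 and polyadenylated RNA was sequenced from 3 wild-type and 3 Fgfr1 FCPG/FCPG libraries, per the labels. The libraries were made with a stranded mRNA kit, per the labels' protocols. The submitters' processing notes name Bowtie, featureCounts, DESeq2, DESeq and the build mm39. Their versions, the annotation release and the strand setting of the counting were not given in the sources used here. The authors deposited raw counts per Ensembl gene ID, as whole numbers, for 56953 features, and these counts were the input of every test. The deposited count table carries 10-5 in each column name, which is not explained, while the labels give day 9.5, and the stage of the labels is used throughout. Columns were matched to samples by genotype letter and replicate number.

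The authors also deposited a DESeq2 table, whose columns are, per the file headers, the mean normalized count (a signal averaged over the libraries), the log2 fold change with its standard error, the Wald score, and the p-value with its adjusted p-value. It was used only to compare the calls.

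A dot and 1 character of the version had been removed from the deposited IDs, so 12804 of them ended in a leftover digit. Cutting every ID to 18 characters left no duplicates, and 52029 of the 56953 IDs matched a gene symbol. These rows held 98.7% of all counts. Gene order and gene overlap were taken from GENCODE M21, which describes an older build than the one the submitters name, so no coordinates are given.

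Whether a row's name matched the reads counted in it was examined without the genotype. A list of 1271 ubiquitously expressed protein-coding genes (ribosomal, proteasomal, respiratory chain, splicing, translation and similar families) was laid out along the chromosomes, and a gene was called detected at a mean of 10 CPM (counts scaled to library size) or more. A hidden Markov model with 2 states set the chance of detection to 0.95 where names match and 0.25 where they do not, with a chance of 0.03 of changing state between neighbours. Runs of at least 6 neighbouring genes with a posterior above 0.95 were kept, from the first to the last gene of the run. They are called retained stretches below. The mitochondrial genome and 4 Y-linked genes were kept too. The list, the detection minimum and the model were chosen after seeing the data, and an earlier list of fewer genes was tried first. In 200 simulations with a planted run of 20 matching genes among the 1271, 78.2% of the planted genes and 0.02% of the other genes were called.

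Libraries were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with filterByExpr by group, TMM normalization, no covariate and no fold minimum, as fixed before the data were examined. This left 14550 features. Calls are at a Benjamini-Hochberg adjusted p below 0.05 over all of them, and log2 fold changes are mutant over wild type with the standard error from the F statistic. CPM values use TMM-scaled library sizes. In counts simulated for this comparison over 14550 features, 76 of 100 features changed 2-fold and 100 of 100 changed 4-fold were recovered, and 5.5% of the calls were unchanged features. All 13 members of a simulated list lowered 2-fold were called lower. The changed features were drawn from those with a mean of at least 5 CPM, and the list from those of at least 100 CPM. Recovery of features with lower counts was thus not tested.

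There were 36 gene lists fixed before the data were examined, of which 33 had at least 5 tested members and were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Only the mitochondrially encoded list had most of its tested members in the retained part, so the results of the other lists are not described by name. Reactome sets were not tested for the same reason. Named genes were chosen by a rule fixed before the data were examined, applied within the retained part only, a restriction added after seeing the data. The rule takes the 12 genes with the largest positive and the 12 with the largest negative log2 fold change among called genes that reached a mean of 5 CPM in the higher group and whose 2 groups did not overlap. It adds up to 4 called members of each fixed list, or 2 members as values where none was called, and leaves predicted genes unnamed.

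Alternatives were DESeq2 size factors, the Wald test of DESeq2 1.42.0, limma-voom, no low-count filter, a filter of 5 CPM in 3 libraries, a replicate block, each library left out in turn, a term for embryo sex, library sizes without erythroid and mitochondrially encoded genes, and a test against a log2 fold change of 0.5. The p-values set the group difference against the spread between these libraries. The labels say nothing of litters, so differences between litters may be mixed with those between genotypes. Library totals ran from 16984568 to 27316475 counts, and errors are given as the spread between libraries.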

Results

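Gene expression was measured by RNA sequencing of tailbud tissue, the posterior end of the embryo that holds neuromesodermal progenitors and newly formed somitic and intermediate mesoderm. There were 3 libraries from wild-type embryos and 3 from embryos homozygous for the Fgfr1 FCPG allele, in which residues of the receptor that bind signaling effectors carry point mutations. The comparison asks how transcription in forming mesoderm differs when this signaling from the receptor is disabled. Total counts per library ranged from 16984568 to 27316475. Y-linked genes averaged 148 CPM in wild-type replicate 1, 225 CPM in mutant replicate 2 and 166 CPM in mutant replicate 3, and at most 0.147 CPM in the other libraries, so the sexes were unevenly spread over the groups.

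Gene names could be read over part of the genome only. Of 1271 ubiquitously expressed genes, 414 reached a mean of 10 CPM. Eef1a1, among the most abundant transcripts of most cells, stood at 0.030 CPM, Hsp90ab1 at 0.018 CPM and Actb at 3.35 CPM, whereas the feature named Ncapd2 stood at 6560 CPM. On 3 stretches, on chromosomes 4, 6 and 15, such genes stood at ordinary levels: 38 of their 39 ubiquitous genes reached 10 CPM, with a median of 274.3 CPM, against 376 of 1232 elsewhere, with a median of 0.83 CPM. These shares follow in part from how the stretches were chosen. Among protein-coding genes that played no part in that choice, 77% of 461 inside and 40.1% of 18273 outside reached 1 CPM. Of genes from families silent in most tissues, such as olfactory receptors, 0 of 12 inside and 128 of 1625 outside did. The 12 inside are too few to tell these shares apart. The bounds are not exact. With a detection minimum of 20 CPM instead of 10 CPM the stretch of chromosome 15, which holds Ctnnd2 and Cdh6, dropped out and that of chromosome 6 ended at Ube2h, before Mest. When gene models were moved along the chromosome, 5 of 13 windows of the stretches gained more than 95% of simulations with unmoved models, 3 of them at distances of 1 to 2.5 kb and 2 at 6 and 7 kb. Names in the stretches are thus not secured gene by gene. They are least sure in the latter 2 windows and at the far end of the chromosome 6 stretch, where Prrt4, Tspan33, Smo and Mest lie. Named genes below come from these stretches, the mitochondrial genome and the Y chromosome, which held 595 of the 14550 tested features and 18.6% of the counts.

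**Figure D1:**
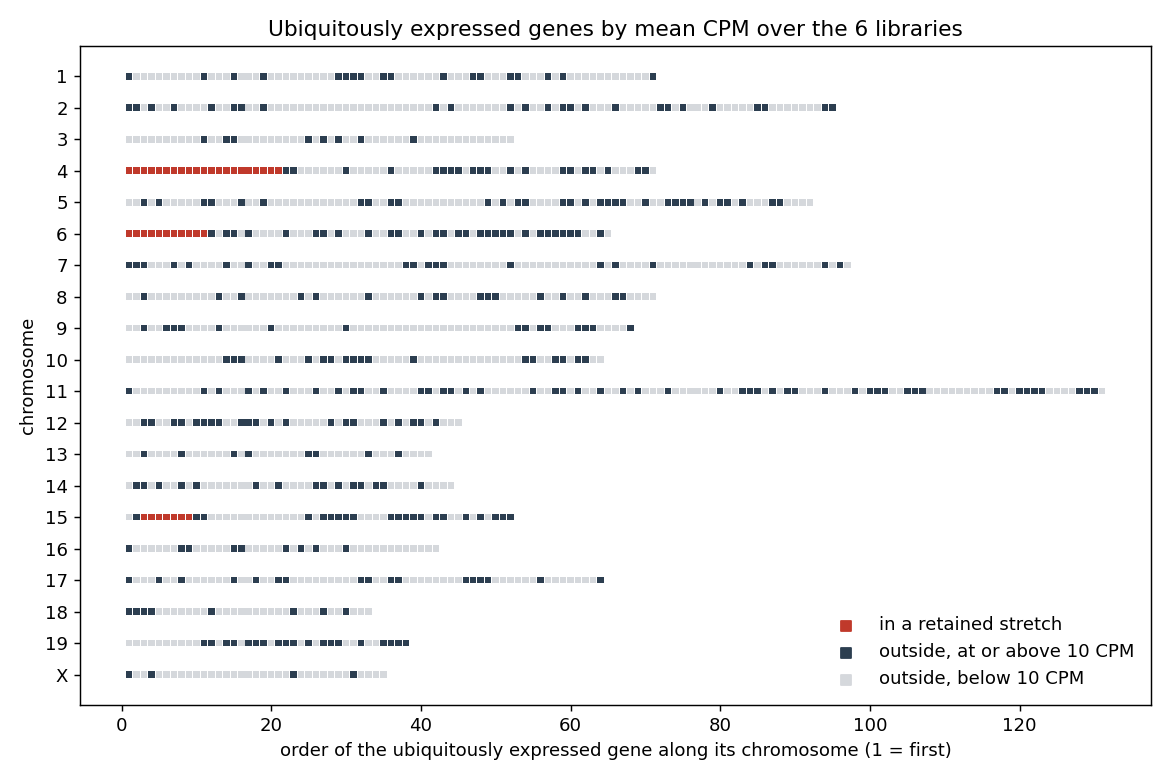
Each square is 1 of the ubiquitously expressed genes, placed by chromosome (vertical axis) and by its order along that chromosome (horizontal axis), and colored by whether its mean over the 6 libraries reached 10 CPM and whether it lay in a retained stretch. Detected genes ran together at or near the start of chromosomes 4, 6 and 15, where 1 of the 39 retained genes was below 10 CPM. Elsewhere they were mostly mixed with undetected ones, but unbroken detected runs occurred there too, such as Usp5 to Ndufa9 on chromosome 6.

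Fgfr1 itself lay outside the retained part. The feature that carries its name stood at 29.1, 29.7 and 26.8 CPM in wild-type replicates 1 to 3 and at 25.3, 29.2 and 28.8 CPM in mutant replicates 1 to 3. These values cannot be read as Fgfr1 expression, and a point mutation need not alter the level of its transcript, so they do not check the labels. The tailbud markers Fgf8 and T, at 0.139 and 0 CPM, lay outside as well, and FGF target genes are not described for the same reason.

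All 13 messenger RNAs encoded in the mitochondrial genome, which specify subunits of the respiratory chain and ATP synthase, were lower in the mutant. Their log2 fold changes ran from -1.43 to -0.78, with a median of -1.05, and the largest adjusted p was 0.024 (edgeR quasi-likelihood test). mt-Nd1, a subunit of complex I, fell from 13260 ± 1201 CPM to 4905 ± 927 CPM (SD, n = 3 per group), a log2 fold change of -1.43 ± 0.14 (SE). mt-Co1, a subunit of cytochrome c oxidase, fell from 29680 ± 5114 CPM to 15600 ± 759 CPM. mt-Cytb fell by 1.22 and mt-Co3 fell by 1.04 on the log2 scale. Together these 13 transcripts took 11.96% ± 1.67 of the counts in wild type and 5.82% ± 0.47 in the mutant (SD, n = 3 per group), with no overlap between the groups. As a list they were lower than the other features with a preset correlation (camera adjusted p = 8.71e-10), but not with an estimated correlation (adjusted p = 0.493). The fry test, which asks whether the genes of a list move one way and does not set them against other features, gave an adjusted p of 0.0171. Adjusted over the list alone, 13 of 13 were lower, though transcripts of the same genome in the same libraries are not independent of each other. The other 3 tested features of the same genome differed among themselves. Counts at the proline transfer RNA gene mt-Tp rose from 94.1 ± 32.8 to 324.2 ± 74.1 CPM, a call lost without wild-type replicate 2 (adjusted p = 0.0576 by edgeR). Those at the ribosomal RNA gene mt-Rnr1 stood at 1092 ± 78.3 and 1122 ± 404.5 CPM (adjusted p = 0.931 by edgeR). Those at the ribosomal RNA gene mt-Rnr2 stood at 1258 ± 287.3 and 748.6 ± 173.6 CPM, lower but not past the threshold (adjusted p = 0.0657 by edgeR). Polyadenylated RNA was sequenced, so counts at these 3 genes need not follow the levels of the mature transfer and ribosomal RNAs. Several of these genes overlap a neighbour, among them mt-Atp6 with mt-Atp8 and mt-Nd4 with mt-Nd4l, so their counts are not fully separate. mt-Co2 lost its call without any 1 of the wild-type replicates, and without wild-type replicate 2 the number of lower transcripts was 10.

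**Figure D2:**
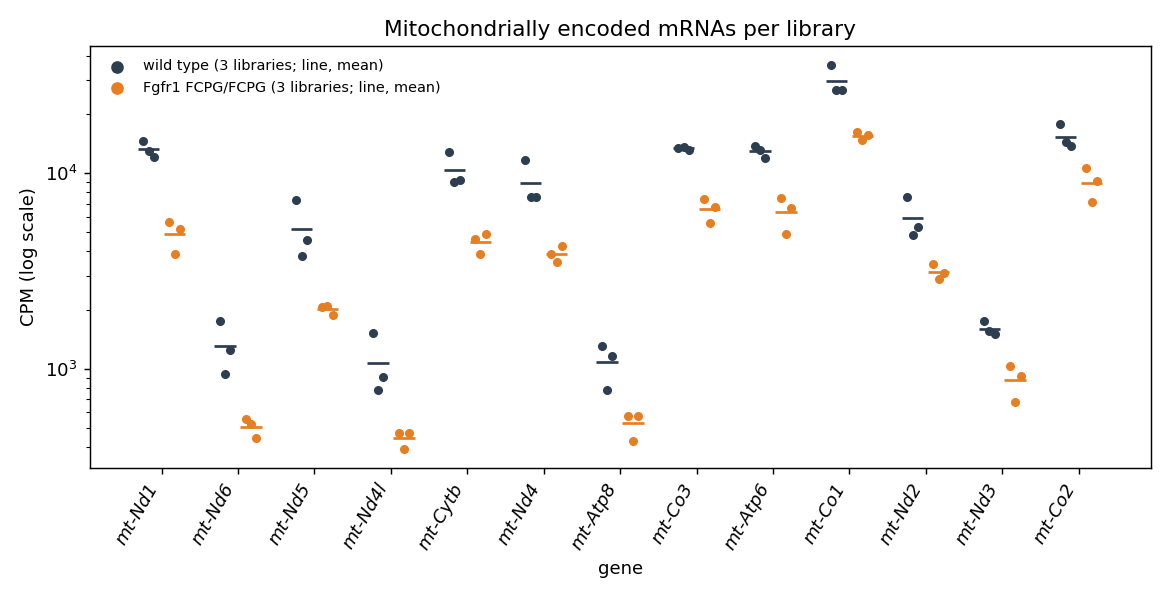
CPM on a log axis for the 13 mitochondrially encoded messenger RNAs in each of the 3 wild-type and 3 mutant libraries, with a line at each group mean. For every transcript the 3 mutant libraries lay below the 3 wild-type libraries, with mt-Nd1 at 12170 to 14550 CPM in wild type and 3873 to 5667 CPM in the mutant.

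Among the 575 tested nuclear genes of the retained part, 52 rose and 24 fell in the mutant. These counts depend on single libraries: the whole retained part, with the mitochondrial genome, had 53 higher and 37 lower features, but 9 and 12 without wild-type replicate 2, of which 10 of the lower were mitochondrially encoded messenger RNAs, and 14 and 17 without wild-type replicate 3, of which 11 were. Among the nuclear genes named by the rule, the largest rises that held in all alternative fits were those of Prrt4, Peg10, Ctnnd2 and Pnrc1. Prrt4 left the retained part without the windows that chose a moved distance, and Ctnnd2 left it with a detection minimum of 20 CPM. Peg10, an imprinted gene of retrotransposon origin needed for placental development, rose from 1537 ± 421 to 4622 ± 210 CPM, a log2 fold change of 1.59 ± 0.18 (SE, adjusted p = 0.00458 by edgeR). Prrt4 rose from 4.98 ± 1.59 to 27.7 ± 8.2 CPM. Ctnnd2, which encodes the adherens junction protein delta-catenin, rose from 24.1 ± 2.5 to 52.7 ± 2.8 CPM, and Pnrc1, a coactivator of nuclear receptors, rose from 217 ± 9.1 to 460.5 ± 58.9 CPM. Asb4, an imprinted gene for a component of a ubiquitin ligase, rose from 70.6 ± 20.8 to 199.8 ± 40.3 CPM, with an adjusted p of 0.0657 in edgeR without wild-type replicate 2.

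Among the named genes that rose, 4 varied widely between mutant libraries. Pou3f2, a transcription factor of neural progenitors and neurons, stood at 7.70 ± 3.74 CPM in wild type and at 49.8, 305.6 and 20.8 CPM in mutant replicates 1 to 3 (log2 fold change 4.01 ± 0.95 SE, adjusted p = 0.0411 by edgeR). Cav1, the main protein of caveolae, stood at 10.4 ± 3.3 CPM in wild type and at 60.03, 185.2 and 19.8 CPM in the mutants. Runx1t1, a transcriptional corepressor, stood at 12.04 ± 9.8 CPM and at 41.9, 127.9 and 51.1 CPM. Col1a2, a chain of type I collagen, rose from 199.3 ± 28.2 to 593.8 ± 321.3 CPM. In all 4 the highest library was mutant replicate 2. The calls of Pou3f2 and Cav1 were lost without any 1 of the wild-type replicates or without mutant replicate 1, with adjusted p of 0.0565 to 0.167 for Pou3f2 and 0.0668 to 0.159 for Cav1 in edgeR. Without mutant replicate 2 both kept their call, but their log2 fold changes fell from 4.01 to 2.19 and from 3.08 to 1.95. Col1a2 lost its call without any 1 of the wild-type replicates or without mutant replicate 2, where its log2 fold change was 1.12, and Runx1t1 lost it in 4 of the 6 such fits. The calls of Pou3f2, Cav1 and Col1a2 also ended with limma-voom and with a term for embryo sex, where their log2 fold changes were 3.50, 2.86 and 1.26. Thsd7a, with a log2 fold change of 1.44, lost its call without wild-type replicate 2 or 3, and Cftr, with 1.26, lost it without any 1 library other than mutant replicate 3 and with the term for embryo sex, where it was 1.24 (adjusted p = 0.0683 by edgeR).

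Hemgn, a nuclear protein of blood-forming cells, was the only retained member of the primitive erythroid list. It had the largest fall among the genes named by the rule of largest change. It dropped from 78.1 ± 21.9 to 16.3 ± 5.9 CPM, a log2 fold change of -2.26 ± 0.29 (SE, adjusted p = 0.00627 by edgeR), and kept its call in all alternative fits, so a marker of blood cells moved with the genotype beside the other changes described here. Tspan33, a tetraspanin, fell from 67.0 ± 11.4 to 27.9 ± 4.4 CPM and kept its call in the same way. Its name is less sure, since it left the retained part without the windows that chose a moved distance. Dync1i1, an intermediate chain of cytoplasmic dynein, fell from 27.8 ± 8.6 to 7.81 ± 3.65 CPM. Aldh1b1, a mitochondrial aldehyde dehydrogenase, fell from 50.8 ± 10.9 to 19.3 ± 9.97 CPM. Dlx6, a homeobox transcription factor of limb and craniofacial development, fell from 20.4 ± 6.9 to 8.18 ± 2.64 CPM, and Tfpi2, an inhibitor of serine proteases, from 6.28 ± 1.40 to 2.63 ± 0.50 CPM. Aldh1b1 and Dlx6 each lost their call in 4 of the 6 fits that leave out 1 library, Tfpi2 in 3 and Dync1i1 in 2, and all of these kept their direction. A term for embryo sex also ended the calls of Aldh1b1, with its log2 fold change at -1.39 against -1.40 before (adjusted p = 0.0766 by edgeR), and of Dlx6, with -1.10 against -1.31 (adjusted p = 0.0806), and limma-voom that of Dlx6 (adjusted p = 0.0577).

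**Figure D3:**
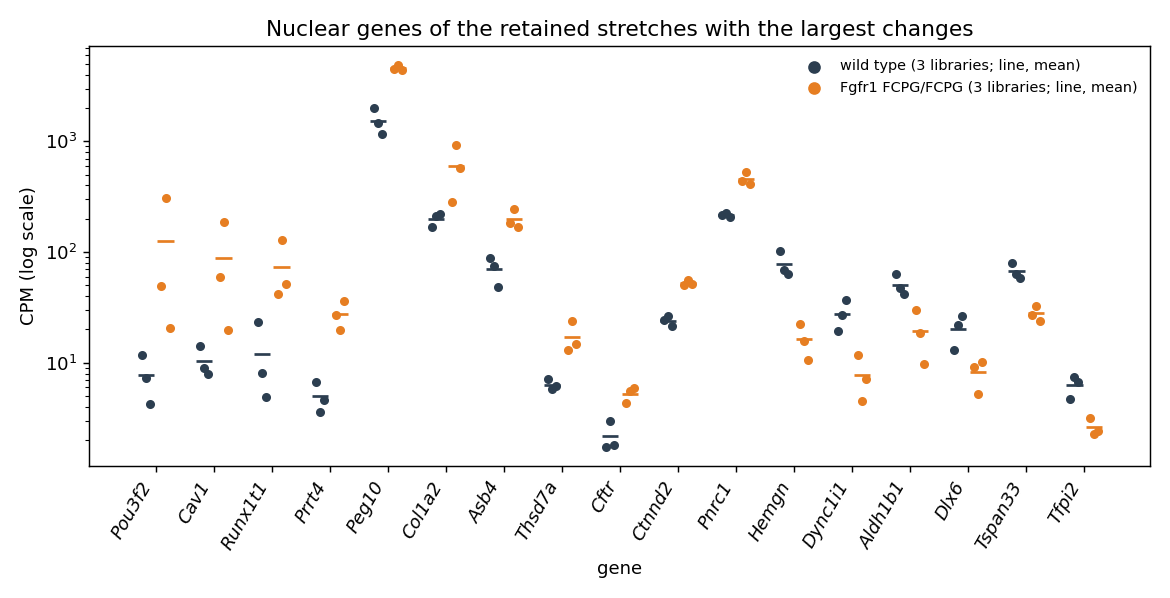
CPM on a log axis for the nuclear genes named by the rule of largest change, in each of the 3 wild-type and 3 mutant libraries, with a line at each group mean. Peg10 lay between 4458 and 4859 CPM in the mutants and between 1155 and 1989 CPM in wild type, whereas Pou3f2 spread from 20.8 to 305.6 CPM among the mutants.

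Few members of the fixed lists lay in the retained part, and most of them did not pass the test. Shb, an adaptor of receptor tyrosine kinase signaling, stood at 147.5 ± 14.3 CPM in wild type and 118.3 ± 22.3 CPM in the mutant (adjusted p = 0.215 by edgeR). Esrp1, a splicing factor of epithelia, stood at 158.3 ± 19.9 and 99.7 ± 27.2 CPM. Wnt2, a Wnt ligand listed with the allantois, stood at 2.91 ± 4.22 and 28.3 ± 8.0 CPM (adjusted p = 0.0584 by edgeR). Its wild-type mean rests on replicate 1, at 7.79 CPM against 0.52 and 0.43 CPM in the other 2; without that library its log2 fold change went from 3.24 to 5.88 and passed (adjusted p = 0.00112), and limma-voom called it as well (adjusted p = 0.0178). The hedgehog receptor component Smo stood at 960.7 ± 14.5 and 901.6 ± 60.2 CPM, and the clathrin light chain Clta at 688.1 ± 9.1 and 817 ± 47.9 CPM. The receptor Met stood at 83.2 ± 38.4 and 79.3 ± 17 CPM and the cadherin Cdh6 at 153.8 ± 22.3 and 194.3 ± 58.7 CPM. The stress genes Trp53inp1, Car9 and Asns had log2 fold changes of -0.55, 0.64 and 0.65, none past the threshold. Esrp1 and Asns passed without mutant replicate 3 and in the DESeq2 Wald test, and Clta and Trp53inp1 passed without mutant replicate 2. Without the low-count filter Wnt2, Cdh6, Esrp1, Trp53inp1 and Asns passed.

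Over all 14550 features, whatever their names, 618 were higher and 534 lower in the mutant at an adjusted p below 0.05 (edgeR). In the retained part, 53 were higher and 37 lower. Without wild-type replicate 2 the counts over all features dropped to 66 higher and 63 lower, and without wild-type replicate 3 to 163 and 151. Without mutant replicate 1 they were 327 and 259, and without wild-type replicate 1 they were 408 and 415. The first principal component took 50.5% of the variance and placed all wild-type libraries below all mutant libraries, which ran from 30.1 to 51.6. Wild-type replicates 1 to 3 lay at -18.1, -40.5 and -55.6, so they were spread along this axis too. Some named genes followed that order among them, such as Peg10 at 1989, 1467 and 1155 CPM. Others, such as Hemgn at 103.3, 68.2 and 62.8 CPM, were farthest from the mutants in replicate 1. Embryo stage and the position of the dissection, left open below for the feature named Hoxb5, were not tested for these genes either. In the authors' deposited table, 998 features were higher and 804 lower. Of the 14439 features in both, 1137 passed in both, all in the same direction, and the Spearman correlation of log2 fold changes was 0.9999 across features, which are not independent replicates. That table carries the same feature names.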

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

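Fits that restrict or widen the retained part were chosen after seeing the data. With a test against a log2 fold change of 0.5, 94 features were higher and 122 lower over the whole table, 8 and 9 in the retained part, and 6 of the 13 mitochondrially encoded transcripts were lower. Among the named nuclear genes that test ended the calls of Pou3f2, Cav1, Runx1t1, Col1a2, Thsd7a and Cftr, which rose. It also ended those of Dync1i1, Aldh1b1, Dlx6 and Tfpi2, which fell. With no low-count filter the counts were 1352 higher and 1145 lower, and 114 and 67 in the retained part. With the term for embryo sex they were 323 and 307, and 26 and 23. The DESeq2 Wald test called 941 higher and 767 lower. Adjusted over the retained genes alone, 81 were higher and 54 lower. A detection minimum of 20 CPM left 445 tested nuclear genes on 2 stretches. The retained part, with the mitochondrial genome, then had 41 higher and 35 lower features. Leaving out the windows that chose a moved distance left 465 tested nuclear genes. The retained part, again with the mitochondrial genome, then had 42 higher and 32 lower features. Leaving out each library in turn gave 66 to 783 higher and 63 to 565 lower, 9 to 69 and 12 to 36 in the retained part, and 10 to 13 mitochondrially encoded transcripts lower. The cause of these differences was not tested, except that such fits hold fewer libraries and the test against a minimum asks for a larger change. Of the 33 gene lists, 4 passed, against 2 to 7 without 1 library, 0 with an estimated correlation and 10 with fry. The mitochondrially encoded list, with a median log2 fold change of -1.05, lost its call with an estimated correlation (adjusted p = 0.493) and kept it in the other fits on which lists were tested; they were not tested with the DESeq2 Wald test or against a minimum. Same-numbered libraries did not deviate together (correlations -0.23, -0.01 and -0.01), which gives no sign that the numbers pair them. A shared litter or day cannot be excluded from so few libraries. With the replicate block, 433 features were higher and 411 lower, and 42 and 35 in the retained part, with Wnt2 called (adjusted p = 0.0355 by edgeR) and Tfpi2 not (adjusted p = 0.0516). The uncalled log2 fold change of Met changed sign, to 0.02 with the replicate block and to 0.11 and 0.32 without mutant replicate 3 and without wild-type replicate 1, within a range of -0.36 to 0.32 over the libraries left out. The Reactome tests with either correlation were not run. Size factors, limma-voom, the stricter filter, library sizes without erythroid and mitochondrially encoded genes and the wider stretches moved no count by more than 1.5 times. Whether changes of genes near the filter limit can be resolved at this depth was not tested.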

Other observations

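The tests in this part were chosen after the results were seen, except those of embryo sex and of other splits of the libraries. The retained stretch of chromosome 6 holds genes listed as imprinted, around Peg10 and around Mest. Imprinted genes are expressed from 1 parental copy in at least some tissues. Counts per gene do not tell the parental copies apart, so imprinting in this tissue was not measured. Mest, whose name is less sure, rose from 2713 ± 496 to 5206 ± 816 CPM (SD, n = 3 per group), Sgce from 104.6 ± 3.4 to 191.4 ± 31.6 CPM and Ppp1r9a from 142.6 ± 17.2 to 206.8 ± 29.9 CPM, beside Peg10 and Asb4. Pon3, Pon2 and Tfpi2 of the same region went the other way: Pon3 fell from 34.3 ± 5.2 to 18.8 ± 2.5 CPM and Pon2 from 116.7 ± 13.5 to 77.3 ± 12.2 CPM. Of 12 tested genes on a list of imprinted genes of the stretches, 5 were higher and 3 lower, against 47 higher and 21 lower of the 563 other nuclear genes (Fisher's exact test, two-sided, p = 2.1e-05). The list was written after several of these genes had been seen to change, and neighbours in a cluster share control, so this p cannot show that imprinted genes changed as a group.

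The lower mitochondrially encoded transcripts did not come from scaling between libraries or from sex alone. DESeq2 size factors and library sizes recomputed without them changed too little to test this, with 13 of 13 lower past the threshold under both. Within a library a scaling factor cancels, and the log2 ratio of their counts to those of the tested nuclear genes of the stretches was 0.47 ± 0.2 in wild type and -0.79 ± 0.17 in the mutant (SD, n = 3 per group), a difference of -1.27. Of those nuclear genes 52 rose and 24 fell, so part of this difference can come from the denominator. The median log2 fold change of the transcripts themselves was -1.05. With the term for embryo sex 12 of the 13 stayed lower past the threshold. Chance could not be tested further, since 3 against 3 libraries make 10 splits: the real split gave 13 lower transcripts and the highest other 0, and for all features 1152 calls against 6 and for the retained part 90 against 4, the real split being the 1 of the 10 as large in each case. Whether RNA quality, the amount of tissue taken or the share of cell types differed between genotypes is open, and so is a response of the tissue to the mutation. Of 7 tested nuclear genes of the stretches with names of respiratory chain or ATP synthase subunits and assembly factors, 1, Ndufa5, was lower past the threshold and 0 were higher.

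A candidate explanation for the missing ubiquitous genes is that gene models and alignments were displaced against each other. In 54 windows of 10 Mb outside the stretches, the gene models were moved by up to 1 Mb in steps of 0.5 kb, and features then lying on exons of protein-coding genes were compared with the rest. In 100% of the windows the best distance was 5 kb or more and scored above every distance of 2 to 3 Mb. Scanned windows that followed each other on a chromosome chose distances within 10 kb of each other in 18 of 37 pairs. At most 8 pairs did so in 10000 shuffles (permutation p = 0.0001, the smallest they can give). Windows with fewer than 8 ubiquitous genes had been skipped, so some pairs lay far apart, such as windows 5 and 11 of chromosome 7. The pairs thus measure agreement along a chromosome rather than between adjacent windows. In simulated windows this scan recovered 18 of 20 distances within 3 kb. An earlier scan on ubiquitous genes alone, which recovered 9 of 20, was above its random sets in 14.8% of the windows. Inside the stretches the scan resolves less: in simulations with unmoved gene models, 8 to 41 of 50 chose a distance of 5 kb or more. Of 13 windows of retained features, 5 gained more from moving than 95% of these simulations, 3 of them at best distances of -1 to -2.5 kb and 2 at distances of 5 kb or more, -6 kb on chromosome 4 and 7 kb on chromosome 6. The window at the far end of the chromosome 6 stretch, scanned with the features beyond it, chose -19.5 kb and scored above every far distance, and its retained features alone chose 3.5 kb, with a gain of 0.86 that was within the simulations (95% at 1.16 or less). Some names in the stretches may therefore not match their reads, most of all in the 2 windows and at that far end; without these 3 windows 42 features of the retained part were higher and 32 lower. Windows picked by hand had been looked at before any scan. Shuffled row names would not leave a run of 18 neighbouring detected genes (permutation p = 0.0001, the smallest that 10000 shuffles can give). Counting on the opposite strand would give high scores to features lying opposite to ubiquitous genes. In the 6 windows where this could be scored, with gene models not moved, the scores ran from -0.89 to 0.36, 0% of them above 3. The same-strand scores of those windows, 0.3 to 2.86, were below 3 too. With displaced gene models neither strand need score high, so this test cannot decide on the strand. Counting on the opposite strand would also have hidden the genes of the stretches, which stood at ordinary levels. No biological explanation was tested.

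The feature named Hoxb5 stood at 25.1, 86.2 and 514.9 CPM in wild-type replicates 1 to 3 and at 0.62, 0.34 and 1.94 CPM in mutant replicates 1 to 3 (log2 fold change -7.66, adjusted p = 0.014 by edgeR). It was singled out after its values were seen. At the best distance of its window, -108 kb, its exons lay on 1475 bases of Hoxb13 exons on the same strand, and 11 of 4001 distances tried put it on Hoxb13. The scan on ubiquitous genes alone chose -103 kb, which put it on none. Its best score there, 6.41, was not above that of the highest random set, 6.47, so that scan cannot decide between the distances. The reads may therefore be those of Hoxb13, a posterior Hox gene of the tail, as a hypothesis that a recount against matching gene models would settle. The wild-type libraries differed widely among themselves, so a difference in embryo stage or in the position of the dissection is open too.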
